A study of Homo sapiens with 35 samples.

How the data were processed

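The data were raw read counts per gene from total RNA sequencing of 35 libraries of HEK293T cells, an established human embryonic kidney line. The counts were deposited by the authors as 1 table with a column per library, described as taken before duplicate removal. Reads were trimmed and aligned, per the submitters' processing notes, with FastQC, cutadapt and STAR on the hg38 build, and no versions were stated. The counting tool, the annotation release and the strand setting were not given in the sources used here. The table held 60665 genes. All 37 genes of the mitochondrial chromosome had 0 counts in every library, so no mitochondrial transcript could be measured and the list of 13 mitochondrially encoded protein genes could not be tested. Gene identifiers were matched to GENCODE release 29, in which 58478 of the 60665 identifiers (96.4%) were found, and this annotation gave the positions on hg38. A symbol can stand for overlapping genes or paralogs in such counts: ACTA2 lies beside FAS on the opposite strand, TM7SF2 overlaps VPS51, STS overlaps PUDP, KRT8 lies beside KRT18, MBD6 lies beside DCTN2 and DDIT3, MARVELD3 overlaps PHLPP2, and ALDOA and ASNS overlap unnamed transcripts. Values of these genes, of HSPA1A and HSPA1B, and of histone, ribosomal protein and small nuclear RNA genes may include reads of their neighbours or paralogs.

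Libraries were grouped by their labels into 15 groups in 3 sets. The first set carried replicate numbers 1 and 2 and held 3 control libraries (1a, 1b and 2) and 2 libraries each with siPOOLs against TSPYL2, ZEB1, ZNF608, ZNF609 and ZNF687. The second set carried numbers 3 and 4 and held 4 control libraries (3a, 3b, 4a and 4b), 2 libraries each for INTS13, HDGF and ZNF655, and glucose-starved libraries of the control (n = 4), INTS13 (n = 2) and HDGF (n = 2). The third set held 2 ZMYND8 libraries and 2 controls labelled for ZMYND8. No label named a control for ZNF655, and the controls of the second set were used. The first-set controls were numbered 1a, 1b and 2 in the titles and 1, 2a and 2b in the descriptions; the 1b and 2 libraries differed by a chi-square of 5.08 per degree of freedom, against 102 for 1a and 1b and 120.1 for 1a and 2, so the numbering of the descriptions was used wherever a replicate block was fitted to this set alone. Libraries of the first set paired by number: in 15 of 15 pairs of groups the difference between number 1 and number 2 correlated across 11515 genes above 0.1 (median r 0.742, range 0.398 to 0.907). The numbers did not pair the second set, where 6 of 21 pairs passed 0.1 (median r 0.0254), and the third set had 1 pair of groups (r 0.103). Starved libraries of ZMYND8, named in the series description, were not analysed here. Nothing in the labels states that replicates were separate cultures, so p-values measure the spread between these samples.

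Genes were filtered with filterByExpr by group, which left 19275, and scaled by TMM. One edgeR quasi-likelihood fit (edgeR 4.0.16, R 4.3.3) of 15 group means with no block gave every comparison as a contrast, so that groups of 2 libraries shared the spread of all (20 residual degrees of freedom, 5.87 prior degrees of freedom, median biological coefficient of variation 0.123). Each contrast used groups of 1 set, except those of ZNF655, INTS13 and HDGF depletion with the controls labelled for ZMYND8. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 19275 genes were called, all tests were two-sided, and adjusted p-values of genes are from edgeR. Levels are TMM-scaled counts relative to library size (CPM) as mean and SD, and log2 fold changes carry their SE. Interactions with starvation were contrasts of the same fit. Gene lists were tested with camera (limma 3.58.1) on voom log2 CPM with a preset correlation of 0.01 and repeated with an estimated correlation, adjusted over the lists of a comparison; log2 CPM used a prior count of 2. Members of a list were counted over all genes tested and also adjusted over the list alone. Correlations across genes were computed on 19266 genes without the siPOOL targets, with no p-value, since genes are not replicates. For depletions sharing the 4 controls, 20 simulated unchanged pairs of groups gave the value that sharing alone produces, and the controls were also split between the depletions.

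The comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule named the siPOOL targets; the 8 called protein-coding genes with the largest change in each direction for INTS13, HDGF and ZMYND8 depletion and for starvation of control cells, and 4 for the other comparisons, with a mean log2 CPM of at least 2 and no overlap between libraries of the groups; up to 4 called members of each list that passed camera; and TXNIP, ARRDC4, HSPA5, ATF4, DDIT3, ASNS, CDH1, FOS, EGR1, NAB2, ZNF592 and ZNF532. Some genes that the rule selected are not reported here by name, and they stay in the counts of calls, list members and named genes. The lists, with members tested, were Integrator subunits (19), small nuclear RNAs (13), replication-dependent histones (42), immediate early genes (39), integrated stress response genes (45), endoplasmic reticulum chaperones (32), glycolysis (23), cholesterol biosynthesis (25), lysosome and autophagy (38), p53 targets (24), cell cycle genes (36), interferon response (26), cytosolic ribosomal proteins (78), epithelial genes repressed by ZEB1 (27), primary cilium (42), neuronal genes (27) and heat shock (17). Markers of other cell types were blood cells (3 tested), hepatocytes (1), fibroblasts (5) and keratinocyte or carcinoma lines (2).

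The tests were tried on simulated counts with the spread of these libraries. With 100 genes changed 2-fold, 83 to 95% were recovered in the depletion and starvation comparisons and 67% in the INTS13 interaction; at 1.5-fold 45 to 73% and 17% were recovered. Between 2.78 and 8.20% of simulated calls were false, and 0 of 20 unchanged lists were called in each comparison. Alternatives tried were DESeq2 size factors, no filter on low counts, a replicate block by either numbering, a and b control libraries summed, fits to libraries of 1 set, the DESeq2 1.42.0 Wald test, each library left out in turn, and for correlations other minimum levels and split controls. DESeq2 size factors moved the median of all genes by at most 0.03 on the log2 scale (ZNF655, -0.03) and changed the sign of the median in 0 of the 108 list tests that passed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.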

Results

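Total RNA was sequenced from HEK293T cells treated for 72 h with 5 nM of a siPOOL, a pool of small interfering RNAs against 1 transcript, or with a control siPOOL. The targets were INTS13, a subunit of the Integrator complex, and 8 proteins studied as its partners: HDGF, ZMYND8, ZNF655, TSPYL2, ZEB1, ZNF608, ZNF609 and ZNF687. Integrator cleaves nascent RNA and ends transcription at many genes, and the depletions addressed how far its functions and those of the partners meet. Control, INTS13-depleted and HDGF-depleted cells were also kept without glucose for 24 h, to ask how the depletions bear on the response to starvation. Ribosomal RNA was depleted and libraries were stranded, with single-end reads. Total counts ran from 16.8 to 50.8 M per library (median 25.6 M). Between 24443 and 27588 genes had at least 1 count in a library.

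Every target fell in its own depletion, with no overlap between depleted and control libraries. HDGF (ENSG00000143321, hg38 chromosome 1, 156742109 to 156766925) dropped to 8.36% of control, 46.2 ± 4.88 CPM (SD, n = 2) against 552 ± 22.9 (n = 4). INTS13 (ENSG00000064102, chromosome 12, 26905181 to 26938326) dropped to 13.9%, 14.2 CPM against 102 ± 3.73. ZEB1 dropped to 32.5%, 18.05 ± 2.59 CPM against 55.5 ± 4.84 (n = 3), and ZNF687 to 35.3%, 18.9 ± 0.362 against 53.6 ± 11.9. TSPYL2 was left at 42.8% of control, ZNF655 at 47.1%, ZNF609 at 48.7%, ZMYND8 at 52.1% and ZNF608 at 56.1%. The adjusted p from edgeR was lowest for HDGF (4.8e-20) and highest for ZMYND8 (0.0114), whose call was lost when any 1 of its 4 libraries was left out. The TSPYL2 call was lost without either TSPYL2 library and the ZNF609 call without either ZNF609 library. With first-set libraries alone and their replicate numbers as a block, the adjusted p was 0.00385 for TSPYL2, 1.75e-05 for ZEB1, 0.0121 for ZNF608, 0.0364 for ZNF609 and 0.0033 for ZNF687. Among the other targets, HDGF fell after INTS13 depletion (log2 fold change -0.23 ± 0.08 SE, adjusted p = 0.0479) and after TSPYL2 depletion (-0.36 ± 0.08, adjusted p = 0.0205, blocked adjusted p = 0.091), and INTS13 fell after ZNF655 depletion (-0.36 ± 0.11, adjusted p = 0.0308). These 3 calls did not withstand leaving out single libraries: HDGF in INTS13 depletion and INTS13 in ZNF655 depletion kept theirs only without control 3a, and HDGF in TSPYL2 depletion only without control 1a or 2.

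**Figure D1:**
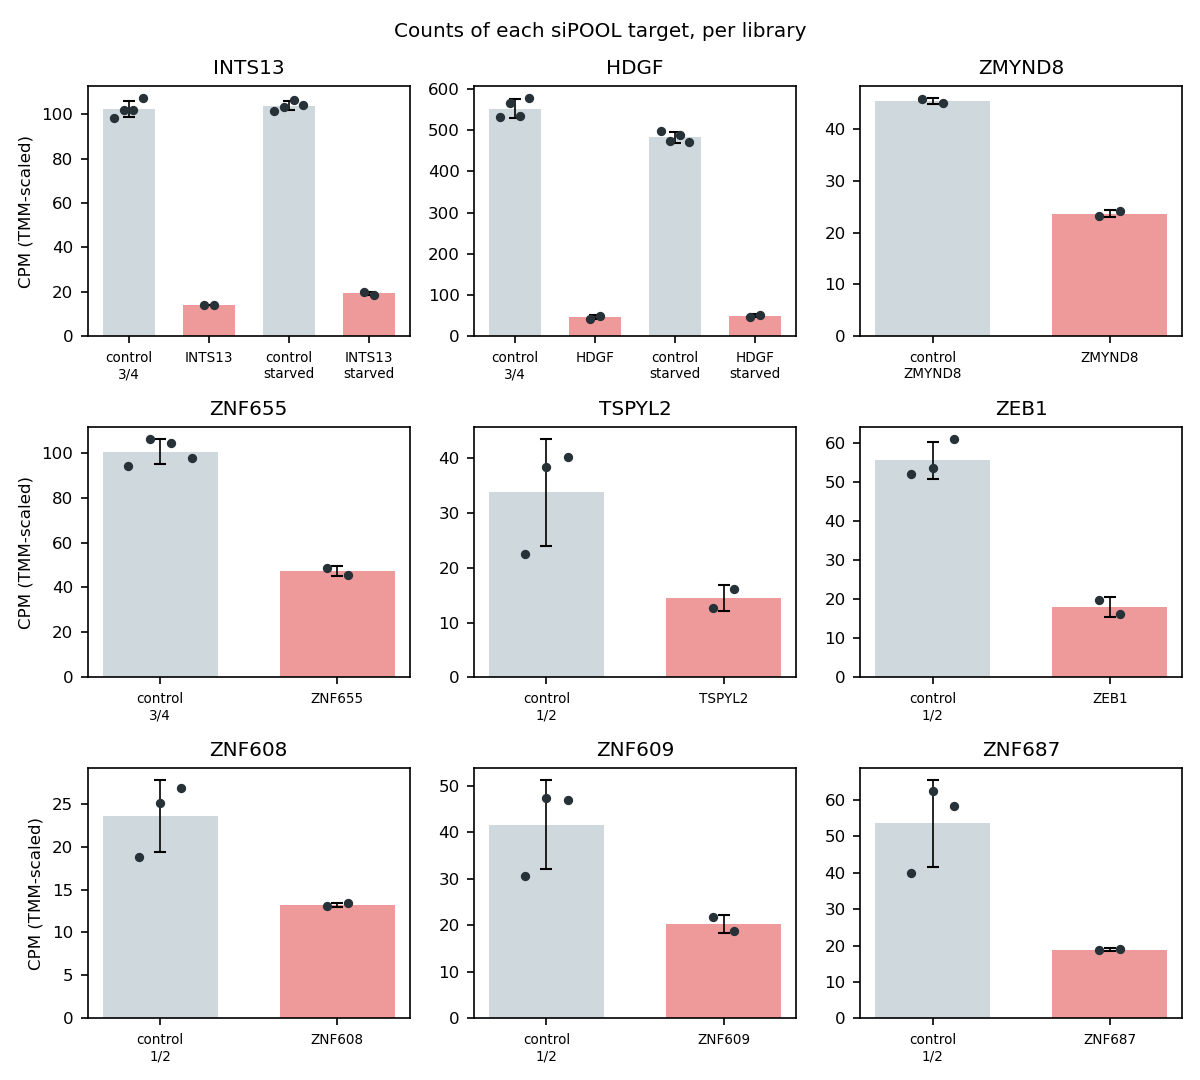
TMM-scaled CPM of each siPOOL target in every library (points), with the mean (bars) and SD (error bars) of depleted and control groups. In all 9 panels the depleted libraries lie below their controls, as for INTS13 at 14.2 CPM against 98.2 to 107 CPM.

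After INTS13 depletion CDKN1A, which encodes the cell-cycle inhibitor p21, rose from 17.9 ± 2.00 CPM (n = 4) to 108 ± 1.60 (n = 2), a log2 fold change of 2.60 ± 0.13 (adjusted p = 2.83e-13). FAS, a death receptor gene, rose from 5.57 ± 0.253 to 26.2 ± 1.27 CPM. SEC23A (chromosome 14, 39031919 to 39109646), a component of the COPII coat of vesicles leaving the endoplasmic reticulum, fell from 244 to 85.2 ± 0.381 CPM (log2 -1.52 ± 0.07, adjusted p = 1.24e-13). SLC1A5, a glutamine transporter gene, fell from 397 ± 14.7 to 123 ± 8.51 CPM. In total 2459 genes were called, 1258 higher and 1201 lower, of which 356 and 82 changed at least 2-fold; 4898 genes had an unadjusted p under 0.05. Leaving out INTS13 library 3 gave 868 calls and leaving out library 4 gave 1034. Of the 46 named genes 27 kept their call with each library left out in turn.

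Of 24 p53 targets, 17 rose after INTS13 depletion, 0 fell and 7 did not pass, and 19 rose when adjusted over the list alone (camera adjusted p = 5.19e-27, and adjusted p = 1.19e-04 with an estimated correlation). Epithelial genes known as targets of repression by ZEB1 also rose: 17 of 27 rose and 1 fell, with the same numbers adjusted over the list alone (adjusted p = 9.76e-11, and 0.00582 with an estimated correlation). They included EPCAM (0.947 to 6.02 CPM, log2 2.65 ± 0.26) and the cadherin gene CDH1 (1.59 ± 0.183 to 8.43 ± 0.256 CPM, log2 2.40 ± 0.38, adjusted p = 8.27e-05). ZEB1 itself had a log2 change of -0.24 ± 0.11 that did not pass (adjusted p = 0.146). Cell cycle genes moved down as a list, with 8 of 36 lower, 2 higher and 26 not passing (13 lower and 2 higher adjusted over the list alone, adjusted p = 4.36e-06, and 0.0038 with an estimated correlation). Members that fell included the mitotic checkpoint genes BUB1 (-0.42) and BUB1B (-0.42) and the replication genes CDC6 (-0.44) and MCM7 (-0.39). The CDC6 call was lost without INTS13 library 3.

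Other lists passed with the preset correlation but not with an estimated one. Cholesterol biosynthesis genes had 6 of 25 lower, such as TM7SF2 (-1.23) and MVD (-0.83), and 8 adjusted over the list alone (adjusted p = 6.67e-05, and 0.421 with an estimated correlation). Glycolysis genes had 5 of 23 lower, including SLC16A1 (-0.47) and LDHA (-0.39), and the glucose transporter gene SLC2A3 higher (0.69), with 6 lower and 1 higher adjusted over the list alone (adjusted p = 4.06e-04, and 0.130 with an estimated correlation). Primary cilium genes had 7 of 42 lower, such as IFT172 (-0.66), and 1 higher, the same adjusted over the list alone (adjusted p = 0.0013, and 0.107 with an estimated correlation). Replication-dependent histones had 3 of 42 lower, also adjusted over the list alone, with a median of -0.36 (adjusted p = 1.69e-04, and 0.626 with an estimated correlation). Heat shock genes had 3 of 17 lower, 4 adjusted over the list alone (adjusted p = 0.041, and 0.475 with an estimated correlation). Ribosomal protein genes had 1 of 78 lower, RPL28 (-0.58), also 1 adjusted over the list alone (adjusted p = 0.001, and 0.873 with an estimated correlation). Integrator subunits, INTS13 included, did not pass as a list (2 of 19 higher and 3 lower, 2 and 4 adjusted over the list alone, median 0.01, adjusted p = 0.549), and 0 of 13 small nuclear RNAs were called by edgeR (adjusted p = 0.815).

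HDGF encodes a nuclear growth factor that binds chromatin. After its depletion GJA1, the gap junction gene for connexin 43, fell from 86.6 ± 5.36 CPM (n = 4) to 24.6 ± 2.14 (n = 2; log2 -1.81 ± 0.12, adjusted p = 3.46e-10). IGDCC3, an immunoglobulin-family membrane gene, fell from 16.4 ± 1.21 to 4.29 ± 0.402 CPM, and FSCN1, which encodes the actin bundler fascin, from 44.4 ± 13.04 to 17.4 ± 0.31. The cyclin gene CCND2 rose from 144 ± 4.49 to 302.5 ± 5.54 CPM (log2 1.07 ± 0.18, adjusted p = 5.96e-04). Of 24 p53 targets 5 rose and 1 fell, also adjusted over the list alone, with FAS (0.97 ± 0.12), SPATA18 (0.83), TNFRSF10B (0.74) and CDKN1A (0.58) among the rises (adjusted p = 0.0318, and 0.958 with an estimated correlation and 0.075 with second-set libraries alone). Primary cilium genes had 3 of 42 lower, BBS4 (-0.60), IFT88 (-0.45) and RPGRIP1L (-0.38), also 3 adjusted over the list alone (adjusted p = 0.00307, and 0.333 with an estimated correlation). Ribosomal protein genes moved down as a list with 0 of 78 called by edgeR (median -0.16, adjusted p = 0.00173, and 0.958 with an estimated correlation). The glucose-responsive gene ARRDC4 rose (0.42 ± 0.12, adjusted p = 0.0376), a call kept only without control 4a among the 6 settings with 1 library left out. In all 866 genes were called, 364 higher and 502 lower, with 3111 at an unadjusted p under 0.05. Leaving out HDGF library 3 gave 264 calls and library 4 gave 283. Of the 25 named genes 17 kept their call with each library left out in turn.

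ZMYND8, a chromatin reader, was compared with the 2 controls labelled for it. PIGS, a gene of glycosylphosphatidylinositol anchor transfer, fell from 95.8 ± 0.0678 to 45.1 ± 0.591 CPM (log2 -1.09 ± 0.08, adjusted p = 1.52e-09, n = 2 each). SLC7A11, a cystine transporter gene, fell from 138 ± 16.3 to 57.4 ± 3.95 CPM (-1.26 ± 0.30, adjusted p = 0.0357). The synaptic vesicle gene SYP rose from 19.7 ± 1.33 to 37.0 ± 0.642 CPM (0.91 ± 0.09, adjusted p = 2.39e-06) and GNG4, a G protein subunit gene, from 24.7 to 48.3 CPM. Neuronal genes rose as a list, with 6 of 27 higher and 7 higher and 1 lower adjusted over the list alone, such as the secretory granule gene CHGB (0.277 to 1.98 CPM), with adjusted p = 9.32e-07 (adjusted p = 0.0475 with an estimated correlation). The p53 targets had 5 of 24 higher and 9 adjusted over the list alone, including ZMAT3 (0.87), TNFRSF10B (0.87) and CDKN1A (0.74), with adjusted p = 4.19e-07 (adjusted p = 0.0475 with an estimated correlation). Integrated stress response genes had 3 of 45 lower, SLC7A11, JDP2 (-1.20) and GPT2 (-0.59), and 18 lower and 1 higher adjusted over the list alone (adjusted p = 5.52e-18, and 0.0475 with an estimated correlation), while ATF4 itself did not pass (-0.56, adjusted p = 0.069). Endoplasmic reticulum chaperones and heat shock genes moved up as lists with 0 members called by edgeR, 4 of 32 and 3 of 17 adjusted over the list alone (0.00206 and 1.65e-04, and 0.160 and 0.105 with an estimated correlation). The 144 calls (86 higher, 58 lower; 1855 at an unadjusted p under 0.05) depended on single libraries. Their number was 17 without control 4, 59 without control 3, 37 without ZMYND8 library 3 and 27 without library 4. PIGS, GNG4, SYP, CHGB, APOLD1 and TNFRSF10B were the 6 of 26 named genes that kept their call throughout.

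ZNF655, a zinc finger gene, was compared with the controls of the second set, since no label names its control. SYP rose from 14.1 ± 1.02 CPM (n = 4) to 42.9 ± 2.33 (n = 2; log2 1.60 ± 0.08, adjusted p = 2.98e-13) and CDKN1A from 17.9 ± 2.00 to 65.8 ± 12.8 CPM (1.88 ± 0.14, adjusted p = 7.97e-10). SNAP23, a membrane fusion gene, fell from 64.4 ± 4.76 to 22.0 ± 1.86 CPM (-1.55 ± 0.11, adjusted p = 7.41e-10). Of 24 p53 targets 15 rose, 16 adjusted over the list alone, led by EDA2R (2.35), PHLDA3 (2.02) and FAS (1.72), with adjusted p = 4.6e-16 (adjusted p = 0.00297 with an estimated correlation). Of 27 neuronal genes 11 rose, 16 adjusted over the list alone, including CHGB (2.29) and MAP2 (1.13), with adjusted p = 1.36e-09 (adjusted p = 0.0177 with an estimated correlation). Interferon response genes had 5 of 26 higher and 1 lower, 7 and 1 adjusted over the list alone, such as the RNA sensor gene IFIH1 (1.03) and OAS3 (1.47), with adjusted p = 0.00788 (adjusted p = 0.0336 with an estimated correlation). Cell cycle genes had 5 of 36 lower, 6 adjusted over the list alone, such as CCNE1 (-0.70), with adjusted p = 0.00137 (adjusted p = 0.0336 with an estimated correlation). Lysosome and autophagy genes had 7 of 38 lower and 2 higher, 8 and 3 adjusted over the list alone, among them CTSA (-0.93), NEU1 (-0.76) and ATG14 (-0.70), with adjusted p = 0.0237 (adjusted p = 0.139 with an estimated correlation and 0.0504 with a replicate block). TXNIP (0.64 ± 0.20, adjusted p = 0.0331) and ARRDC4 (0.58 ± 0.12, adjusted p = 0.00137), glucose-responsive genes, rose. TXNIP kept its call only without control 4a among the 6 settings with 1 library left out, and neither gene passed against the controls labelled for ZMYND8 (0.59 ± 0.23, adjusted p = 0.114, and 0.22 ± 0.14, adjusted p = 0.339).

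Further lists moved down after ZNF655 depletion with the preset correlation alone. Ribosomal protein genes had 5 of 78 lower and 1 adjusted over the list alone, with a median of -0.39 (adjusted p = 1.21e-11, and 0.453 with an estimated correlation). Glycolysis genes had 4 of 23 lower and 1 higher, also adjusted over the list alone (adjusted p = 0.0155, and 0.327 with an estimated correlation). Cholesterol biosynthesis genes had 3 of 25 lower, 4 adjusted over the list alone (adjusted p = 0.00137, and 0.444 with an estimated correlation). Heat shock genes had 3 of 17 lower, also 3 adjusted over the list alone (adjusted p = 0.0091, and 0.313 with an estimated correlation). Histones had 0 of 42 by edgeR (median -0.23, adjusted p = 0.00371, and 0.599 with an estimated correlation). The 2208 calls (1267 higher, 941 lower; 4623 at an unadjusted p under 0.05) depended on single libraries. Their number was 721 without ZNF655 library 3 and 1076 without library 4. With DESeq2 size factors 1109 were higher and 1198 lower, with the DESeq2 Wald test 1186 and 1483, and with second-set libraries alone 2535 and 2978. Of the 45 named genes 21 kept their call with each library left out in turn. Against the controls labelled for ZMYND8 1755 genes were called (995 higher, 760 lower), of which 757 were among the 2208. Named genes, and lists other than the p53 targets, were tested against those controls after the values were seen. There 26 of the 45 named genes kept their call and 0 changed direction, and MAP2 (adjusted p = 0.137), IFIH1 (0.625), CCNE1 (0.207) and ATG14 (0.194) were among the 19 that lost it. Of the 10 lists that had passed, 6 did so again, and 4 others passed with the preset correlation alone: integrated stress response genes (8 of 45 lower and 1 higher, adjusted p = 5.72e-07, and 0.289 with an estimated correlation), endoplasmic reticulum chaperones (5 of 32 higher, 0.00104 and 0.243), small nuclear RNAs (0 of 13 by edgeR, median -1.05, 0.00344 and 0.499) and cilium genes (3 of 42 lower and 1 higher, 0.0277 and 0.289). Of the 6 only p53 targets passed with an estimated correlation (11 rose, adjusted p = 2.98e-10 and 0.0293). Neuronal (5 rose, 1 fell, 0.00629 and 0.291), histone, glycolysis, cholesterol and ribosomal protein genes did not (0.243 to 0.379). Interferon (0.490), cell cycle (0.357) and lysosome genes (0.357) did not pass, and heat shock genes had the opposite direction (adjusted p = 0.815).

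The first set compared 5 further partners with 3 controls, and its number 1 libraries stood apart. Ribosomal protein genes took 13.4% of counts in control 1a against 8.95% in 1b and 8.97% in 2. In libraries 1 and 2 of the depletions the shares were 16.9 against 9.25% for ZEB1, 14.8 against 10.0% for ZNF687, 12.05 against 9.27% for ZNF608, 11.5 against 10.2% for ZNF609 and 10.5 against 7.52% for TSPYL2. The replicate numbers were therefore also fitted as a block: over all 35 libraries with the numbering of the descriptions, the calls became 3533 for TSPYL2 (1513 higher, 2020 lower), 2630 for ZEB1 (1431 and 1199), 1668 for ZNF608, 430 for ZNF609 and 225 for ZNF687, and these held every gene called without a block. With first-set libraries alone and the block, a test chosen after the values were seen, the calls were 50, 322, 333, 36 and 7 (39, 292, 264, 29 and 7 of them shared with the fit of all libraries without a block). Blocked adjusted p-values given for single genes are from this fit.

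TSPYL2 encodes a nucleosome assembly protein. After its depletion SEC23A dropped from 311 ± 15.3 CPM (n = 3) to 123 ± 3.64 (n = 2; log2 -1.34 ± 0.07, adjusted p = 8.65e-12, blocked adjusted p = 1.92e-05), and the vesicle fusion gene VAMP3 from 122 ± 16.3 to 69.7 ± 0.978 CPM (-0.80 ± 0.10, blocked adjusted p = 0.0181). PLAT (-0.90, blocked adjusted p = 0.042) and TM7SF2 (-0.72, blocked adjusted p = 0.035) fell. Rises were those of KMT2D (39.2 ± 7.31 to 94.8 ± 57.6 CPM), ATN1 (1.25), MBD6 (1.12) and NFIC (1.10), and these 4 lost their calls with the block (0.0536 to 0.0633). Glycolysis genes had 3 of 23 lower, PFKFB4 (-0.55), PGK1 (-0.50) and GAPDH (-0.38), and 10 adjusted over the list alone (adjusted p = 2.44e-09, and 0.0246 with an estimated correlation); the blocked adjusted p of these 3 genes was 0.0573 to 0.106. Cell cycle genes had 2 of 36 lower, 6 lower and 1 higher adjusted over the list alone (adjusted p = 1.82e-04, and 0.0246 with an estimated correlation). Of 45 integrated stress response genes 2 fell, 15 lower and 1 higher adjusted over the list alone (adjusted p = 1.39e-10, and 0.156 with an estimated correlation). Cholesterol biosynthesis genes had 1 of 25 lower, 3 adjusted over the list alone (adjusted p = 9.26e-05, and 0.392 with an estimated correlation). Lysosome genes had 2 of 38 lower and 1 higher, 3 and 1 adjusted over the list alone (adjusted p = 0.0293, and 0.156 with an estimated correlation and 0.0744 with the block). Histone and ribosomal protein lists moved down with 0 members called by edgeR (medians -0.39 and -0.35; 2.45e-08 and 2.44e-09, and 0.489 and 0.512 with an estimated correlation), and the ribosomal protein share of TSPYL2 library 1 was 10.5% against 7.52% in library 2. The 428 calls (219 higher, 209 lower; 3238 at an unadjusted p under 0.05) depended on single libraries. Their number was 12 without TSPYL2 library 2 (2 higher, 10 lower), 800 without library 1 (588 and 212), 256, 185 and 267 without controls 1a (84 and 172), 1b (92 and 93) and 2 (144 and 123), and 3397 without all number 1 libraries (1419 and 1978). With no filter on low counts it was 609 (463 higher, 146 lower), 224 of them among the 428. SEC23A, VAMP3 and TM7SF2 were the 3 of 21 named genes that kept their call with each library left out.

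ZEB1 is a repressor of epithelial genes. After its depletion EPCAM rose from 2.04 ± 0.507 CPM (n = 3) to 7.82 ± 0.325 (n = 2; log2 1.93 ± 0.25, adjusted p = 2.36e-05, blocked adjusted p = 7.71e-04) and SPINT2 from 49.1 ± 8.19 to 129.5 ± 39.2 CPM (1.40 ± 0.14, adjusted p = 8.79e-07, blocked adjusted p = 8.99e-05). Of 27 epithelial genes 11 rose and 0 fell, 15 adjusted over the list alone (adjusted p = 4.7e-12, and 0.00469 with an estimated correlation), while CDH1 at 11.3 ± 7.30 against 5.06 ± 2.28 CPM did not pass (adjusted p = 0.0677, blocked adjusted p = 0.00362). CDKN1A rose from 22.0 ± 2.32 to 61.4 ± 10.5 CPM (1.48 ± 0.14, adjusted p = 7e-07, blocked adjusted p = 6.49e-06), and 15 of 24 p53 targets rose, 17 rose and 1 fell adjusted over the list alone, among them PHLDA3 (1.37), EDA2R (1.15) and SPATA18 (1.04), with adjusted p = 2.59e-15 (adjusted p = 0.00363 with an estimated correlation). FCGRT (-1.13), ZADH2 (-1.08), LRRC58 (-1.08) and ACVR2B (-1.18) fell with blocked adjusted p-values of 2.23e-04 to 0.00583. Integrated stress response genes had 3 of 45 lower, SLC7A11 (-0.999), ALDH1L2 (-0.54) and GPT2 (-0.51), and 11 adjusted over the list alone (adjusted p = 5.78e-06, and 0.417 with an estimated correlation), and the blocked adjusted p of these 3 genes was 0.106 to 0.147. Histones had 2 of 42 higher and 14 adjusted over the list alone (median 0.55, adjusted p = 2.61e-09, and 0.567 with an estimated correlation). Small nuclear RNAs had 0 of 13 by edgeR (median 0.83, adjusted p = 0.0119, and 0.698 with an estimated correlation). Ribosomal protein genes had 0 of 78 with 78 positive values (median 0.50, adjusted p = 1.97e-10, and 0.698 with an estimated correlation); ribosomal protein genes took 16.9% of counts in ZEB1 library 1 and 9.25% in library 2. Interferon genes had 1 of 26 higher, also adjusted over the list alone, IFIH1 (1.27), with adjusted p = 0.0134 (adjusted p = 0.0602 with an estimated correlation; blocked adjusted p of the gene 0.0677). The 726 calls (343 higher, 383 lower; 4255 at an unadjusted p under 0.05) depended on single libraries. Their number was 112 without ZEB1 library 1, 7292 without library 2, and 4080, 282 and 242 without controls 1a, 1b and 2, and 681 without all number 1 libraries (383 of them among the 726). With each library left out in turn 12 of 20 named genes kept their call.

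After ZNF608 depletion SYP rose from 23.5 ± 1.27 CPM (n = 3) to 50.04 ± 2.11 (n = 2; log2 1.09 ± 0.08, adjusted p = 3.94e-09, blocked adjusted p = 2.46e-04) and STMN3, a neuronal microtubule regulator gene, from 31.6 ± 0.933 to 61.9 CPM (0.97 ± 0.12, blocked adjusted p = 0.00135). ASNS, the asparagine synthetase gene, fell from 8.45 ± 3.25 to 3.38 ± 0.32 CPM (-1.33 ± 0.24, adjusted p = 0.00183, blocked adjusted p = 0.0311). Of 27 neuronal genes 7 rose and 0 fell, 11 adjusted over the list alone, including CHGB (2.18) and SCG3 (1.76), with adjusted p = 7.36e-11 (adjusted p = 0.021 with an estimated correlation). Of 45 integrated stress response genes 12 fell and 1 rose, 27 and 1 adjusted over the list alone, such as CTH (-0.91), SLC7A11 (-1.34) and CHAC1 (-2.42), whose blocked adjusted p was 0.0578, 0.087 and 0.0761 (adjusted p = 4.27e-17, and 0.0742 with an estimated correlation). Immediate early genes had 3 of 39 higher and 1 lower, 8 and 1 adjusted over the list alone, EGR2 (1.21), DUSP2 (0.88) and JUNB (0.80) against JUN (-0.47), with adjusted p = 3.28e-04 (adjusted p = 0.296 with an estimated correlation). The p53 targets had 5 of 24 higher, 7 higher and 1 lower adjusted over the list alone, including TIGAR (0.67) and CDKN1A (0.58), with adjusted p = 7.49e-05 (adjusted p = 0.105 with an estimated correlation). Of 17 heat shock genes 2 rose, also adjusted over the list alone, DNAJB1 (0.53) and DNAJA1 (0.59), with adjusted p = 3.28e-04 (adjusted p = 0.105 with an estimated correlation). Lysosome genes had 2 of 38 lower and 1 higher, 7 and 1 adjusted over the list alone (adjusted p = 0.0269, and 0.105 with an estimated correlation). Glycolysis genes had 1 of 23 lower, also adjusted over the list alone, the lactate transporter gene SLC16A1 (668 ± 96.3 to 375.2 ± 9.46 CPM), with adjusted p = 0.0481 (adjusted p = 0.432 with an estimated correlation and 0.135 with the block). Small nuclear RNAs moved up with 0 of 13 called by edgeR (median 0.38, adjusted p = 0.0298, and 0.813 with an estimated correlation and 0.106 with the block), where ribosomal protein shares were 12.05 and 9.27% in ZNF608 libraries 1 and 2. The 532 calls (208 higher, 324 lower; 2785 at an unadjusted p under 0.05) depended on single libraries. Their number was 170 without ZNF608 library 1, 162 without library 2, 289 without control 2 and 1809 without all number 1 libraries. Of the 27 named genes 8 kept their call with each library left out.

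ZNF609 is a paralog of ZNF608. After its depletion ZCCHC12 rose from 42.3 ± 7.38 CPM (n = 3) to 77.4 ± 4.78 (n = 2; log2 0.87 ± 0.14, adjusted p = 0.00254, blocked adjusted p = 0.00529) and PHTF2 from 40.1 ± 5.197 to 64.7 ± 5.17 CPM (0.69 ± 0.10, adjusted p = 4.48e-04, blocked adjusted p = 0.0091), while the mitotic kinase gene NEK7 fell from 89.0 ± 16.1 to 50.9 ± 6.08 CPM (-0.81 ± 0.16, blocked adjusted p = 0.00405). Immediate early genes had 2 of 39 higher, EGR2 (1.60) and JUNB (0.91, blocked adjusted p = 0.0712), and 9 higher and 1 lower adjusted over the list alone (adjusted p = 4.88e-07, and 0.297 with an estimated correlation), while FOS did not pass (1.63, adjusted p = 0.107, blocked adjusted p = 0.00529). Integrated stress response genes had 3 of 45 lower, GPT2 (-0.69), PCK2 (-0.69) and PHGDH (-0.45), and 18 lower and 1 higher adjusted over the list alone (adjusted p = 1.14e-17, and 0.134 with an estimated correlation), and the blocked adjusted p of these genes was 0.112 to 0.211. Histones and small nuclear RNAs moved up with 0 members called by edgeR (medians 0.12 and 0.40; 0.0139 and 0.0375, and 0.630 with an estimated correlation for both), where ribosomal protein shares were 11.5 and 10.2%. The 110 calls (37 higher, 73 lower; 1891 at an unadjusted p under 0.05) depended on single libraries. Their number was 9 without ZNF609 library 1, 27 without library 2, 278, 56 and 33 without controls 1a, 1b and 2, and 2817 without all number 1 libraries. With each library left out in turn, 0 of 13 named genes kept their call every time.

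ZNF687 encodes a zinc finger protein. After its depletion SMARCD2, a subunit gene of the SWI/SNF chromatin remodelers, fell from 143 ± 14.1 CPM (n = 3) to 51.2 ± 0.753 (n = 2; log2 -1.49 ± 0.09, adjusted p = 1.04e-10, blocked adjusted p = 1.48e-05). The deubiquitinase gene USP12 (-0.84, blocked adjusted p = 0.00464) and CEMIP2 (-0.80, blocked adjusted p = 0.0392) fell, BMPER (-0.93) did so without the block alone (blocked adjusted p = 0.0543), and PHTF2 rose from 40.1 ± 5.197 to 69.3 ± 4.66 CPM (0.79 ± 0.10, blocked adjusted p = 0.00458). The zinc finger genes ZNF592 (-0.29 ± 0.15, adjusted p = 0.572) and ZNF532 (-0.32, adjusted p = 0.415), named in advance, did not pass. Histones had 1 of 42 higher and 11 adjusted over the list alone (median 0.49, adjusted p = 1.05e-17, and 0.494 with an estimated correlation). Small nuclear RNAs had 0 of 13 by edgeR (median 0.80, adjusted p = 5.5e-05, and 0.570 with an estimated correlation) and ribosomal protein genes 0 of 78 with 78 positive values (median 0.33, adjusted p = 8.09e-12, and 0.570 with an estimated correlation); ribosomal protein shares were 14.8 and 10.0% in ZNF687 libraries 1 and 2. Immediate early genes had 1 of 39 higher and 4 adjusted over the list alone (adjusted p = 5.74e-05, and 0.494 with an estimated correlation). Heat shock genes had 0 of 17 by edgeR and 1 adjusted over the list alone (adjusted p = 4.81e-04, and 0.494 with an estimated correlation). Integrated stress response genes had 0 of 45 by either count (median -0.18, adjusted p = 0.00316, and 0.570 with an estimated correlation). This list moved down in every first-set depletion, all against the same 3 controls, and high controls were not excluded. The 49 calls (13 higher, 36 lower; 1751 at an unadjusted p under 0.05) depended on single libraries. Their number was 7 without ZNF687 library 1, 24 without library 2, 136, 25 and 24 without controls 1a, 1b and 2, and 432 without all number 1 libraries. With no filter on low counts it was 218 (135 higher, 83 lower), 27 of them among the 49. SMARCD2, PHTF2 and ZNF687 were the 3 of 9 named genes that kept their call with each library left out.

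**Figure D2:**
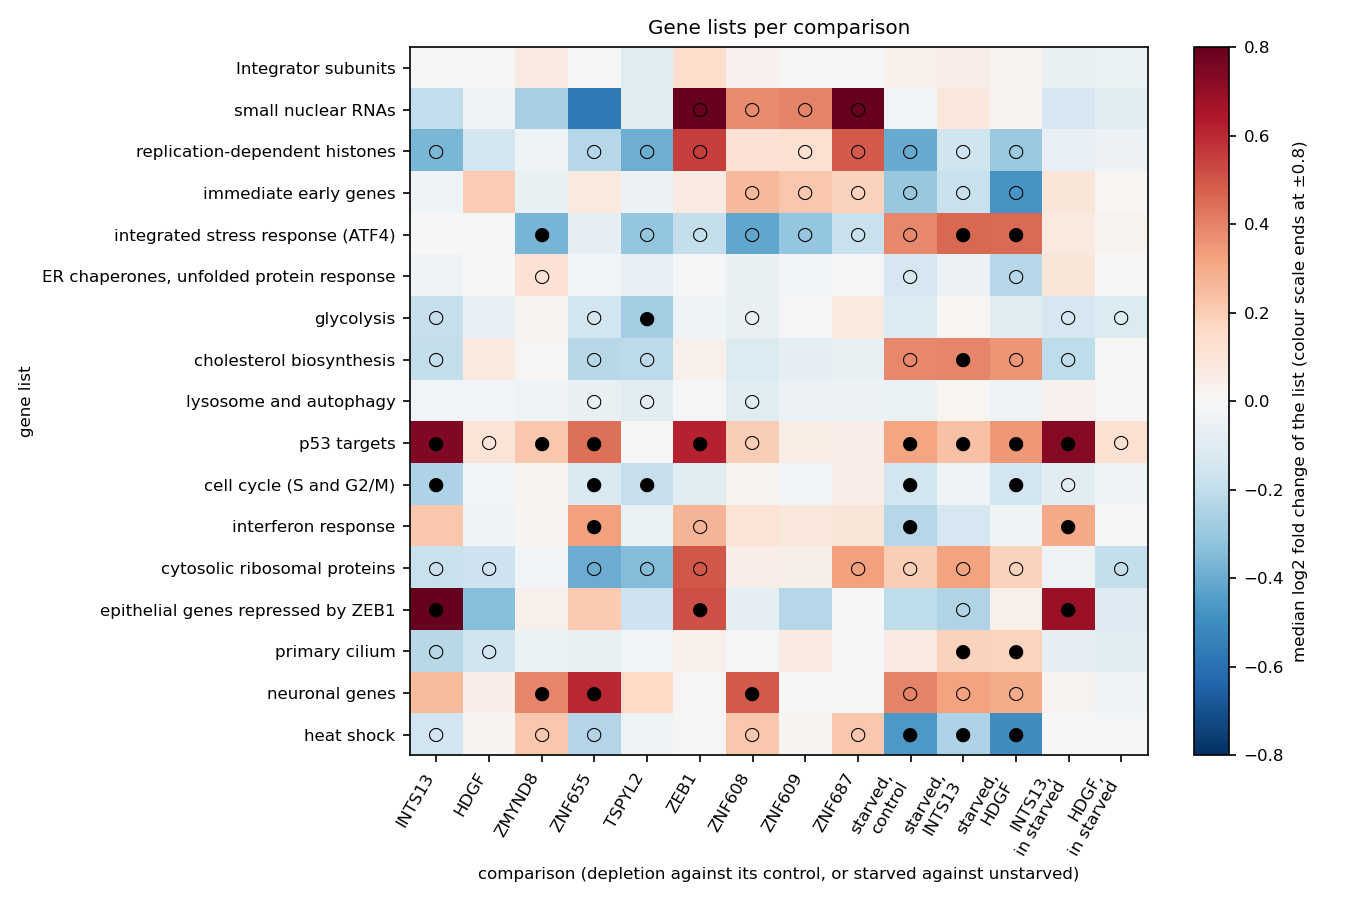
Median log2 fold change of each gene list (colour) in each comparison, where open circles mark a camera adjusted p under 0.05 with the preset correlation and filled circles mark those that also passed with an estimated correlation. The p53 targets had medians of 0.74 for INTS13, 0.62 for ZEB1 and 0.44 for ZNF655.

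In control cells starved of glucose, TXNIP and ARRDC4, which the glucose sensor MondoA activates, fell from 21.2 ± 2.47 to 5.32 ± 0.811 CPM (log2 -1.99 ± 0.18, adjusted p = 8.95e-08) and from 21.1 ± 1.66 to 11.7 ± 0.956 CPM (-0.84 ± 0.10, adjusted p = 2.87e-06), with n = 4 in each group. The linker histone gene H1-3 fell from 188 ± 11.9 to 58.4 ± 4.86 CPM (-1.69 ± 0.12) and HSPA5, the main chaperone gene of the endoplasmic reticulum, from 403 ± 57.4 to 238 ± 22.9 CPM (-0.76 ± 0.12, adjusted p = 9.78e-05). ASNS rose from 6.69 ± 0.375 to 10.7 ± 0.707 CPM (0.68 ± 0.18, adjusted p = 0.0112) and CHAC1, which degrades glutathione, from 6.97 to 19.2 CPM (1.47 ± 0.35), while DDIT3 did not pass (0.58, adjusted p = 0.0532). In all 3243 genes were called, 1691 higher and 1552 lower, 250 and 95 of them at least 2-fold, with 5542 at an unadjusted p under 0.05; leaving out any 1 library gave 2408 to 3009. With a and b libraries summed, which left 2 libraries in each group, starvation of control cells gave 1095 calls, INTS13 depletion 1704 and ZNF655 depletion 1474. Of the 57 named genes 47 kept their call with each library left out; HDGF (-0.19 ± 0.06), ATF4 (0.31 ± 0.10) and ZNF592 (0.35) were among those that did not.

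Of 45 integrated stress response genes 25 rose and 0 fell under starvation, 28 rose and 1 fell adjusted over the list alone (camera adjusted p = 3.88e-12, and adjusted p = 0.0687 with an estimated correlation). Of 24 p53 targets 15 rose, 17 adjusted over the list alone, including PHLDA3 (1.16) and DDB2 (0.83), with adjusted p = 1.77e-10 (adjusted p = 0.00881 with an estimated correlation). Cell cycle genes had 10 of 36 lower, 15 adjusted over the list alone, such as the mitotic kinase gene AURKA (-0.50) and CENPE (-0.81), with adjusted p = 2.48e-05 (adjusted p = 0.00881 with an estimated correlation). Of 17 heat shock genes 11 fell and 1 rose, 12 and 1 adjusted over the list alone, such as BAG3 (-0.70), with adjusted p = 2.29e-09 (adjusted p = 0.00881 with an estimated correlation). Interferon genes had 7 of 26 lower and 1 higher, 8 and 1 adjusted over the list alone, with EPSTI1 (-1.40) lower and ISG15 (0.86) higher (adjusted p = 0.00282, and 0.0196 with an estimated correlation). The following lists passed with the preset correlation alone. Cholesterol biosynthesis genes had 12 of 25 higher, 17 adjusted over the list alone, including MVD (0.58) and LSS (0.54), with adjusted p = 8.09e-09 (adjusted p = 0.121 with an estimated correlation). Histones had 17 of 42 lower and 1 higher, 18 and 1 adjusted over the list alone (adjusted p = 1.24e-09, and 0.294 with an estimated correlation). Immediate early genes had 12 of 39 lower and 1 higher, 15 and 1 adjusted over the list alone, such as DUSP5 (-1.04) and IER3 (-0.84), with adjusted p = 3.46e-05 (adjusted p = 0.163 with an estimated correlation). Endoplasmic reticulum chaperones had 10 of 32 lower, 11 adjusted over the list alone, such as SDF2L1 (-0.69), with adjusted p = 4.21e-04 (adjusted p = 0.122 with an estimated correlation). Neuronal genes had 9 of 27 higher and 1 lower, 12 and 2 adjusted over the list alone, such as CACNA1B (1.54) and BSN (1.07), with adjusted p = 2.48e-05 (adjusted p = 0.0687 with an estimated correlation). Ribosomal protein genes had 1 of 78 higher, RPL28 (0.33), and 0 adjusted over the list alone (adjusted p = 0.00223, and 0.694 with an estimated correlation).

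**Figure D3:**
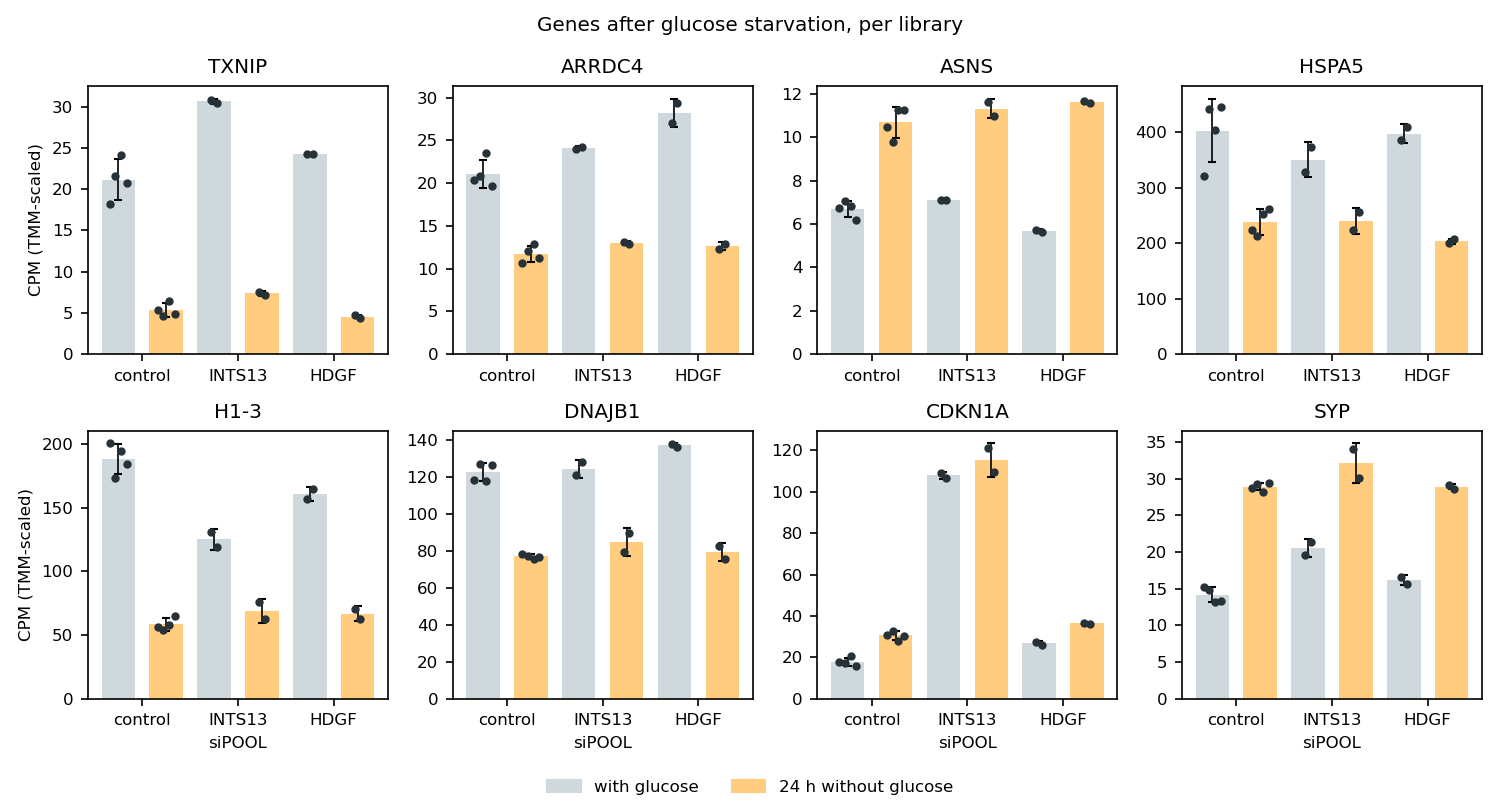
TMM-scaled CPM of 8 genes in control, INTS13-depleted and HDGF-depleted cells with glucose and after 24 h without it (points, libraries; bars, means; error bars, SD). TXNIP fell with each of the 3 siPOOLs, as from 21.2 to 5.32 CPM in control cells.

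Starvation of INTS13-depleted cells lowered TXNIP from 30.7 ± 0.325 to 7.35 ± 0.338 CPM (log2 -2.06 ± 0.25, adjusted p = 1.11e-04, n = 2 each) and ARRDC4 (-0.89). CYP1B1 rose from 7.91 ± 0.863 to 18.4 ± 1.19 CPM (1.21 ± 0.17), the cystathionine lyase gene CTH from 21.7 ± 3.37 to 49.95 ± 6.07 CPM (1.21 ± 0.24), and the cyclin gene CCND1 (-1.04) fell. Integrated stress response genes had 6 of 45 higher and 28 adjusted over the list alone, such as PCK2 (0.74; adjusted p = 1.03e-21). Cholesterol genes had 3 of 25 and 13 higher, such as SQLE (0.68; 1.44e-13). The p53 targets had 1 of 24 and 2 higher, BBC3 (0.76; 1.53e-06). Cilium genes had 1 of 42 and 3 higher, TMEM231 (0.61; 4.29e-05). Heat shock genes had 1 of 17 and 5 lower, DNAJB1 (-0.56; 1.52e-05); each of these 5 lists had an adjusted p = 0.0479 with an estimated correlation. Histones had 2 of 42 lower and 5 adjusted over the list alone (adjusted p = 3.2e-04, and 0.527 with an estimated correlation). Epithelial genes had 1 of 27 lower by both counts, KRT8 (-0.76), with adjusted p = 0.00525 (adjusted p = 0.209 with an estimated correlation). Neuronal genes had 1 of 27 higher, SYP (0.64), and 8 higher and 1 lower adjusted over the list alone (adjusted p = 0.0018, and 0.199 with an estimated correlation). Immediate early and ribosomal protein genes had 0 called by edgeR (medians -0.18 and 0.32; 0.00206 and 3.94e-09, and 0.291 and 0.473 with an estimated correlation). The 255 calls (165 higher, 90 lower; 2408 at an unadjusted p under 0.05) depended on single libraries. Their number was 22 and 14 without INTS13 library 3 or 4 and 36 and 8 without starved INTS13 library 3 or 4. TXNIP and CYP1B1 were the 2 of 22 named genes that kept their call throughout.

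Starvation of HDGF-depleted cells lowered TXNIP from 24.3 to 4.55 ± 0.234 CPM (log2 -2.41 ± 0.27, adjusted p = 1.52e-05, n = 2 each), ARRDC4 (-1.16) and HSPA5 (398 ± 16.9 to 204 ± 4.47 CPM, -0.97 ± 0.18). HRK, a gene that promotes apoptosis, rose from 12.1 to 31.6 ± 0.91 CPM (1.38 ± 0.14, adjusted p = 2.99e-06), and JDP2 (1.75), CHAC1 (1.78), CTH (1.35) and ASNS (1.04) rose as well. Of 45 integrated stress response genes 16 rose, 22 adjusted over the list alone (adjusted p = 1.31e-16, and 0.0328 with an estimated correlation), and 6 of 24 p53 targets, 15 adjusted over the list alone (adjusted p = 6.57e-11, and 0.00797 with an estimated correlation). Heat shock genes had 6 of 17 lower, 12 lower and 1 higher adjusted over the list alone, such as DNAJB1 (-0.79), with adjusted p = 6.41e-11 (adjusted p = 0.00797 with an estimated correlation). Cell cycle genes had 3 of 36 lower and 4 adjusted over the list alone, such as CDC20 (-0.52), with adjusted p = 2.3e-05 (adjusted p = 0.00797 with an estimated correlation). Cilium genes had 2 of 42 higher and 4 adjusted over the list alone, IFT140 (0.61) and BBS2 (0.58), with adjusted p = 7.04e-05 (adjusted p = 0.0328 with an estimated correlation). With the preset correlation alone, endoplasmic reticulum chaperones had 2 of 32 lower and 3 adjusted over the list alone (adjusted p = 5.82e-06, and 0.05004 with an estimated correlation). Immediate early genes had 4 of 39 and 14 lower (adjusted p = 1.73e-08, and 0.0598 with an estimated correlation). Histones had 6 of 42 and 7 lower (adjusted p = 6.47e-09, and 0.301 with an estimated correlation). Cholesterol genes had 3 of 25 and 8 higher (adjusted p = 1.73e-08, and 0.106 with an estimated correlation). Neuronal genes had 4 of 27 higher by both counts, such as SYP (0.84), with adjusted p = 1.33e-04 (adjusted p = 0.0861 with an estimated correlation). Ribosomal protein genes had 0 of 78 by edgeR (median 0.18, adjusted p = 0.00846, and 0.797 with an estimated correlation). The 683 calls (403 higher, 280 lower; 3083 at an unadjusted p under 0.05) depended on single libraries. Their number was 139 and 141 without HDGF library 3 or 4 and 208 and 109 without starved HDGF library 3 or 4, and 9 of 40 named genes, TXNIP, ARRDC4, HSPA5 and HRK among them, kept their call throughout. Of the 255 genes called in INTS13-depleted cells 244 moved in the same direction in control cells, with 135 called higher in both (14.5 by chance) and 69 called lower in both (7.25 by chance), and of the 683 in HDGF-depleted cells 667 did (309 and 235 called in both, against 35.4 and 22.5 by chance).

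In starved cells INTS13 depletion again raised CDKN1A, from 30.5 ± 2.05 CPM (n = 4) to 115 ± 8.15 (n = 2; log2 1.92 ± 0.13, adjusted p = 5.02e-10), and FAS (1.88 ± 0.11), and lowered SLC1A5 from 442 ± 4.46 to 219 ± 21.2 CPM (-1.01 ± 0.12). VAV1 (1.67) rose and AMOTL2 (-1.32) fell. Of 24 p53 targets 17 rose, 19 adjusted over the list alone (adjusted p = 1.38e-36, and 1.35e-05 with an estimated correlation). Of 27 epithelial genes 8 rose, 14 adjusted over the list alone, such as EPCAM (2.70 ± 0.30) and CDH1 (1.24 ± 0.46 to 5.14 ± 0.116 CPM), with adjusted p = 1.64e-13 (adjusted p = 0.0026 with an estimated correlation). Interferon genes had 4 of 26 higher, 5 adjusted over the list alone, such as IFIH1 (1.38) and SAMD9 (1.14), with adjusted p = 0.0108 (adjusted p = 0.0378 with an estimated correlation). Cholesterol genes had 4 of 25 lower and 5 adjusted over the list alone (adjusted p = 3.17e-05, and 0.366 with an estimated correlation). Glycolysis genes had 1 of 23 and 2 lower (adjusted p = 0.0108, and 0.354 with an estimated correlation). Cell cycle genes had 2 of 36 lower by both counts (adjusted p = 0.0138, and 0.111 with an estimated correlation). INTS13 itself was at 19.3 ± 0.77 CPM against 104 ± 2.00, 18.6% of the starved control. The 744 calls (448 higher, 296 lower; 3061 at an unadjusted p under 0.05) depended on single libraries. Their number was 153 without starved INTS13 library 3 and 252 without library 4. Of the 26 named genes 16 kept their call with each library left out.

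In starved cells HDGF depletion lowered GJA1 from 52.0 ± 2.32 CPM (n = 4) to 22.9 ± 0.247 (n = 2; log2 -1.18 ± 0.12, adjusted p = 1.93e-06) and IGDCC3 from 15.7 ± 0.321 to 5.31 ± 0.0514 CPM (-1.56 ± 0.21), and raised LGALS3BP (1.11 ± 0.17) and FAS (0.75 ± 0.12). The p53 targets had 2 of 24 higher, FAS and TNFRSF10B (0.40), and 5 adjusted over the list alone (adjusted p = 0.0258, and 0.917 with an estimated correlation). Glycolysis and ribosomal protein genes moved down with 0 members called by edgeR (medians -0.11 and -0.19; 0.0200 and 8.81e-06, and 0.917 and 0.987 with an estimated correlation). HDGF itself was at 49.5 ± 3.77 against 483 ± 12.7 CPM, 10.2% of the starved control. The 127 calls (51 higher, 76 lower; 2126 at an unadjusted p under 0.05) depended on single libraries. Their number was 25 without either starved HDGF library and 73 without starved control 4b. GJA1, IGDCC3, LGALS3BP, FAS and HDGF were the 5 of 10 named genes that kept their call throughout.

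The interaction asked whether a depletion acted differently in starved cells. For INTS13 it passed for 3 genes, each with a smaller fall in starved cells. SEC23A fell by 1.52 ± 0.07 with glucose and by 0.81 ± 0.07 without it (interaction 0.70 ± 0.10, adjusted p = 0.00207). MSRB3 (chromosome 12, 65278643 to 65491430), a methionine sulfoxide reductase gene, fell by 1.03 ± 0.09 with glucose, and its value without glucose, -0.24 ± 0.09, did not pass (interaction 0.79 ± 0.13, adjusted p = 0.0184). KCTD20 (chromosome 6, 36442767 to 36491143) fell by 0.89 ± 0.08 and 0.30 ± 0.08 (interaction 0.60 ± 0.11, adjusted p = 0.0372). The 3 calls became 0 without starved INTS13 library 3, 1 without starved INTS13 library 4, INTS13 library 4, control 4a or starved control 3a, and 7 without control 3a; 1103 genes had an unadjusted p under 0.05. The number was 46 with DESeq2 (37 positive and 9 negative interactions), 13 with title numbers as a block (8 and 5) and 307 with second-set libraries alone (208 and 99), each with the 3 among them. It was 1 of the 3 with a and b libraries summed, and 3 other genes (1 and 2) without a filter on low counts. No gene list kept its INTS13 interaction with an estimated correlation: the p53 targets (0 of 24 called, 5 lower adjusted over the list alone, 4.5e-04, and adjusted p = 0.325 with an estimated correlation) and neuronal genes (0 of 27, 3 lower adjusted over the list alone, 0.0131, and 0.364 with an estimated correlation) moved down. In the same test (preset, then estimated correlation) histones (4.5e-04; 0.690), cell cycle genes (0.00119; 0.0855), ribosomal proteins (0.0131; 0.873), heat shock (0.0184; 0.364), cilium (0.0417; 0.364) and endoplasmic reticulum chaperone genes (0.0439; 0.505) moved up with 0 members called, or 1 each for histones and heat shock adjusted over the list alone. For HDGF the interaction was called by edgeR for 0 genes, with 909 at an unadjusted p under 0.05, 7 called by DESeq2 and 41 called with second-set libraries alone. Over the 2458 other genes called for INTS13 with glucose, 2328 (94.7%) had the same sign in starved cells, with a slope through the origin of 0.544. Over the 865 for HDGF, 806 (93.2%) did, with a slope of 0.435.

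**Figure D4:**
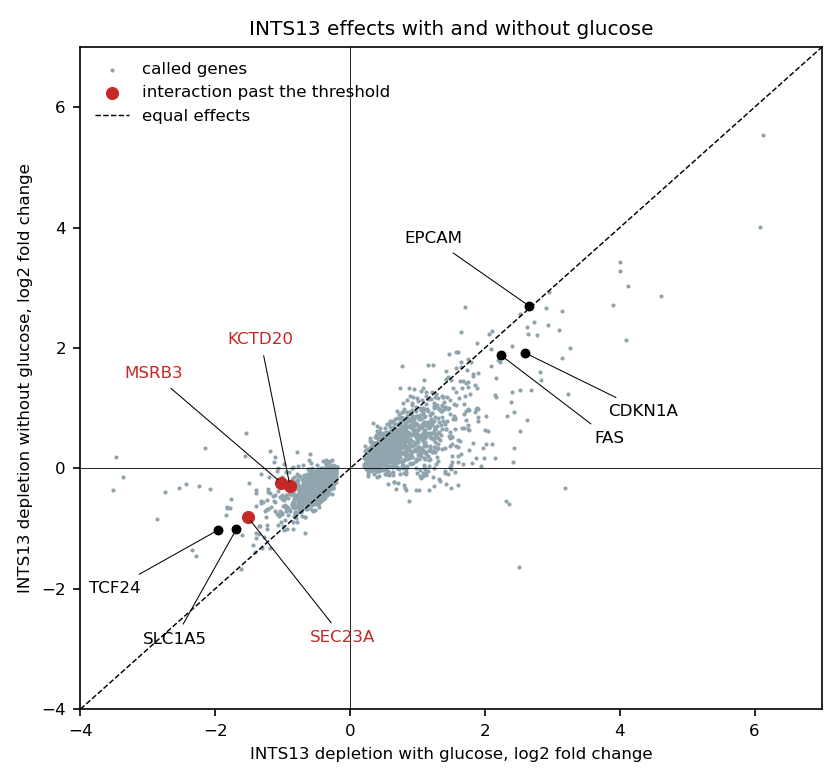
Log2 fold change after INTS13 depletion without glucose (y) against that with glucose (x) for the 2458 genes called with glucose; the dashed line marks equal effects and red points the 3 genes whose interaction passed. SEC23A lies at -1.52 with glucose and -0.81 without.

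Fold changes of INTS13 depletion were correlated across 19266 genes with those of each partner. Pearson's r was 0.4999 for ZNF655 (Spearman's rho 0.481), 0.312 for HDGF (0.321), 0.167 for TSPYL2 (0.224), 0.149 for ZMYND8 (0.144), 0.0887 for ZEB1 (0.0282), 0.0700 for ZNF608 (0.0577), 0.0289 for ZNF609 (0.0263) and -0.0251 for ZNF687 (-0.0298). INTS13, HDGF and ZNF655 shared 4 controls, and simulated unchanged groups sharing them had a mean r of 0.323 (SD 0.0137) and a covariance of 0.0289, against covariances of 0.0596 for HDGF and 0.108 for ZNF655. With the controls split between the depletions r was 0.166 for HDGF and 0.322 for ZNF655, and 0.198 for ZNF655 against the controls labelled for ZMYND8, a test chosen after the values were seen. The ZNF608 value ran from 0.0215 without control 1a to 0.103 without control 2 (0.0354 without ZNF608 library 2). The values of ZNF609 and ZNF687 changed sign with 1 library left out (-0.0150 without control 1a and -0.0131 without ZNF609 library 1; 0.0150 without control 2 and 0.0141 without ZNF687 library 1). The ZEB1 value was 0.00639 without ZEB1 library 2, 0.0398 without control 1a and at most 0.128, the TSPYL2 value 0.104 without TSPYL2 library 2, and the ZMYND8 value 0.0889 without ZMYND8 library 4.

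Chance for INTS13 overlaps takes genes as equally likely to be called and may be too low. With controls split, 193 genes were higher in both INTS13 and ZNF655 depletion (30.8 by chance) and 159 lower in both (23.2), and 71 and 87 for HDGF (7.28 and 11.7 by chance). For ZNF655 against the controls labelled for ZMYND8, chosen after the values were seen, 213 were higher in both (65.0 by chance) and 202 lower (47.2). Partners with controls of their own shared 121 higher and 90 lower genes for ZEB1 (22.4 and 23.8 by chance), 62 and 84 for ZNF608 (13.6 and 20.1), 44 and 66 for TSPYL2 (14.3 and 12.9), 48 and 22 for ZMYND8 (5.62 and 3.55), 18 and 19 for ZNF609 (2.42 and 4.48) and 6 and 9 for ZNF687 (0.849 and 2.18). Genes called in opposite directions were fewer than by chance for TSPYL2 (13 against 27.1) and ZEB1 (34 against 46.3), but not for ZNF608 (42 against 34.0) or ZNF687 (6 against 3.09). Markers of other cell types gave few calls: fibroblast markers missed the camera threshold in every comparison (lowest adjusted p = 0.0870, ZNF609), with 1 of 5 higher after INTS13 and after ZNF655 depletion and 1 lower with starvation of control cells. Blood cell (3 tested), hepatocyte (1) and keratinocyte or carcinoma line markers (2) were too few to test, with 1 keratinocyte or carcinoma marker higher in INTS13 and in ZEB1 depletion and 1 blood cell marker lower after starvation of control and of HDGF-depleted cells. Adjusted over the list alone, both keratinocyte or carcinoma markers were higher after INTS13 and after ZMYND8 depletion (medians 2.47 and 2.42) and 1 after ZNF655, ZEB1, ZNF608 and ZNF609 depletion, and 1 was lower in starved INTS13-depleted and HDGF-depleted cells, and after HDGF depletion under starvation.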

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

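Tests chosen only after the result was seen were the INTS13 and HDGF comparisons with the controls labelled for ZMYND8 and the test of a weaker INTS13 depletion in starved cells; the others were chosen before. Among 154 measures in the 2 groups of 4 control libraries, 15 of 308 sets of 4 values held 1 library far from the others, by the ratio of the gap to the nearest library over the whole range (Dixon's 95% limit for 4 values). Chance marks about 1 in 20 such groups, 15.4 of 308, so this number gives no sign of a deviating library. With glucose, control 4b was apart for SLC1A5 (ratio 0.846; 374.9 CPM against 401 to 406), LDHA (0.868; 1120.2 against 935 to 959), HSP90AA1 (0.890; 2006 against 1548 to 1598) and TNFRSF10B (0.882; 48.8 against 53.4 to 54.0), control 3a for FSCN1 (0.841; 63.7 against 34.9 to 39.5) and RPL13 (0.863; 1926 against 1415 to 1485), and control 4a for BBS4 (0.848; 40.4 against 36.2 to 36.9). Among starved controls, 4b was apart for KRT8 (0.935; 3.55 against 4.00 to 4.03) and RPL28 (0.947; 473 against 425 to 427), 4a for RAB25 (ratio 1; 0.0748 against 0), PMVK (0.902; 22.1 against 25.4 to 25.8) and DDX58 (0.877; 7.03 against 7.89 to 8.01), 3a for STS (0.926; 5.86 against 7.19 to 7.29) and HSPA6 (0.851; 0.961 against 0.280 to 0.381), and 3b for MLH3 (0.855; 3.56 against 4.38 to 4.51). The INTS13 effect differed between fed and starved cells, by a test of the interaction, for SEC23A (0.70), MSRB3 (0.79) and KCTD20 (0.60). For starvation of controls, the real split of 8 into 4 and 4, 1 of 35, called 3243 genes and the others 0. The others mix starved and fed libraries, raising their spread, so they cannot exclude chance.

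Number 1 libraries of the first set shared a profile in all 6 groups: the difference between number 1 and number 2 correlated between groups at 0.398 or more. Gene length as the whole cause is argued against, since the lowest correlation was 0.454 after the trend on exonic length was removed, although the difference did follow length (median rho -0.422, and -0.0154 to -0.505 by group). A few abundant gene families are argued against too, with 0.381 after 414 of their genes were removed. A difference in culture, handling or library preparation between number 1 and number 2 stays open, as the labels name no batch and no biological explanation was tested.

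The p53 targets were higher in several depletions, with medians of 0.74 for INTS13, 0.62 for ZEB1 and 0.44 for ZNF655. Low levels in the second-set controls are argued against for ZNF655, whose median against the controls labelled for ZMYND8 was 0.42 (camera adjusted p = 2.98e-10, 11 rose), and for INTS13 (0.69, adjusted p = 2.22e-17, 18 rose), but for HDGF the median there was 0.0376 (adjusted p = 0.796; 3 rose, 2 fell), so low controls could account for the small HDGF value. An equal response to any siPOOL is argued against by a median difference of 0.54 between ZEB1 and ZNF687 depletion (adjusted p = 4.12e-21). A graded one stays open. Effects of single siPOOLs outside their target stay open, since each target had 1 pool, and no protein was measured.

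Among genes chosen by their change with glucose, effects of INTS13 and HDGF depletion were smaller in starved cells. Choice of genes by their change in glucose is argued against, since with genes chosen on number 3 libraries and measured on number 4 the starved median was 0.621 of that with glucose for INTS13, and 0.661 with the numbers exchanged (HDGF 0.524 and 0.575). Starvation of control cells having moved the same genes is argued against by a ratio of 0.692 and 0.712 among genes that starvation moved by under 0.1. A weaker depletion in starved cells stays open, and the values of both targets go with it: the interaction of INTS13 itself was 0.42 ± 0.16 (edgeR unadjusted p = 0.0138, adjusted p = 0.711 over all genes), and that of HDGF itself 0.29 ± 0.11 (unadjusted p = 0.0132, adjusted p = 0.922). A changed need for either protein in starved cells stays open as well and was not tested.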

How the results depend on the processing

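Tests chosen only after the result was seen were first-set libraries alone with the description numbers as a block, the first set without its number 1 libraries, and, against the controls labelled for ZMYND8, the correlation, named genes and lists other than the p53 targets of ZNF655. Of 165 whole-list values under alternatives other than leaving out a library, 79 stayed within their limit (1.5 times a count, or 1 SD of a correlation), 84 moved and 2 reversed. Named genes kept their direction and their call in 390 of 390 cases with title numbers as a block, 90 of 90 with description numbers over all 35 libraries, 385 of 390 with DESeq2 size factors and 377 of 378 with the DESeq2 Wald test. With first-set libraries alone and description numbers as a block, 48 of 89 kept their call and 41 lost it. With each library left out in turn, 645 of 2206 values lost their call, over 214 genes, and 0 reversed. Where a group was left with 1 library, that library was assumed to vary like the others. Gene lists kept their call in 32 of 108 cases with an estimated correlation and 104 of 108 with a block. Against the controls labelled for ZMYND8, ZNF655 depletion kept 757 of 2208 calls, 26 of 45 named genes and 6 of 10 lists, and heat shock reversed (adjusted p = 0.815); the cause was not tested.

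With libraries of the same set alone, calls were 5624 for INTS13, 2981 for HDGF, 5513 for ZNF655, 1560 for ZMYND8, 1 for TSPYL2, 28 for ZEB1, 10 for ZNF608, 1 for ZNF609 and 1 for ZNF687; 6479, 2371 and 3170 for starvation of control, INTS13-depleted and HDGF-depleted cells; 3047 and 1460 for INTS13 and HDGF under starvation; and 307 and 41 for their interactions. The first set alone has the spread of its number 1 libraries in the residual, and in the other sets that spread is left out. The title numbers as a block gave 283 for ZMYND8, 685 for TSPYL2, 3988 for ZEB1, 1000 for ZNF608, 359 for ZNF609, 283 for ZNF687, 547 and 1129 for starvation of INTS13-depleted and HDGF-depleted cells, 1178 and 253 for INTS13 and HDGF under starvation, and 13 for the INTS13 interaction. The description numbers as a block gave 3533 for TSPYL2, 2630 for ZEB1, 1668 for ZNF608, 430 for ZNF609 and 225 for ZNF687, and with first-set libraries alone 50, 322, 333, 36 and 7. Without all number 1 libraries TSPYL2 had 3397, ZNF608 1809, ZNF609 2817 and ZNF687 432. Number 1 minus number 2 differences correlated in the first set (0.398 to 0.907 by description, 0.355 to 0.885 by title). Second-set pairs had -0.431 to 0.294 and the ZMYND8 pair 0.103, so blocked and unblocked first-set values are given.

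Summing libraries a and b gave 518 for HDGF, 62 for TSPYL2, 436 for ZEB1, 65 for ZNF609, 17 for ZNF687, 1095 for starvation of control cells, 377 and 41 for INTS13 and HDGF under starvation and 1 for the INTS13 interaction, with fewer libraries. The DESeq2 Wald test gave 326 for ZMYND8, 910 for TSPYL2, 1303 for ZEB1, 930 for ZNF608, 321 for ZNF609, 204 for ZNF687, 538 for starvation of INTS13-depleted cells, 352 for HDGF under starvation, 46 for the INTS13 interaction and 7 for the HDGF interaction; the cause was not tested. Without a filter on low counts ZEB1 had 1915 (64.0% higher, against 47.2%), ZNF609 166 and ZNF687 218 (61.9% higher, against 26.5%), and the share of higher genes was 76.0% for TSPYL2 (against 51.2%) and 51.9% for HDGF under starvation (against 40.2%); the cause was not tested. The direction with more calls changed in some settings. The share of higher genes was 51.2% for INTS13, and 45.2 to 49.4% with DESeq2 size factors, the Wald test, the title block, libraries summed or second-set libraries alone, and 45.4% without INTS13 library 3. For ZNF655 it was 57.4%, and 48.1, 44.4 and 46.0% with size factors, the Wald test and second-set libraries (48.3% without ZNF655 library 3), and for starvation of control cells 52.1%, and 48.1, 47.2 and 48.9%, or 49.7% summed. It was 47.5% for ZMYND8 with the Wald test (against 59.7%). For TSPYL2 it was 41.6% with the Wald test, 46.6 and 42.8% with the title and description blocks and 48.4% summed, and for ZEB1 55.4 and 54.4% with these blocks, with 2447 of 4080 without control 1a and 3722 of 7292 without ZEB1 library 2. Without all number 1 libraries it was 41.8% for TSPYL2, 50.5% for ZNF608 (against 39.1%) and 52.9% for ZNF609 (against 33.6%).

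Over genes with a mean log2 CPM of at least 3, the correlation with INTS13 was 0.379 for HDGF, 0.262 for ZMYND8, 0.278 for TSPYL2, 0.108 for ZNF608 and 0.0806 for ZNF609. Over genes called for INTS13 it was 0.463 for HDGF, 0.443 for ZMYND8, 0.714 for ZNF655, 0.302 for TSPYL2, 0.438 for ZEB1, 0.308 for ZNF608 and 0.168 for ZNF609, and reversed to 0.0937 for ZNF687. Without a filter it was 0.370 for HDGF, 0.0275 for ZMYND8, 0.417 for ZNF655, 0.0488 for TSPYL2 and 0.0200 for ZNF608, and reversed to 0.00344 for ZNF687; the cause was not tested. Split controls, which remove the shared libraries, gave 0.166 for HDGF and 0.322 for ZNF655, and the controls labelled for ZMYND8 gave 0.198 for ZNF655.

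With 1 library left out at a time, calls ran as follows: 868 to 2262 for INTS13, 264 to 730 for HDGF, 17 to 59 for ZMYND8, 721 to 2211 for ZNF655, 12 to 800 for TSPYL2, 112 to 7292 for ZEB1, 162 to 715 for ZNF608, 9 to 278 for ZNF609, 7 to 136 for ZNF687, 2408 to 3009, 8 to 36 and 109 to 208 for starvation of control, INTS13-depleted and HDGF-depleted cells, 153 to 567 and 25 to 93 for INTS13 and HDGF under starvation, and 0 to 7 and 0 to 0 for their interactions. The correlations ran from 0.209 to 0.367 for HDGF, 0.0889 to 0.152 for ZMYND8, 0.387 to 0.551 for ZNF655, 0.104 to 0.187 for TSPYL2, 0.00639 to 0.128 for ZEB1, 0.0215 to 0.103 for ZNF608, -0.0150 to 0.0653 for ZNF609 and -0.0704 to 0.0150 for ZNF687. Those of ZNF609 and ZNF687 reversed, as given in the Results. Genes below the filter on low counts were tested only in the setting without it, and what depth limits was not tested.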

Other observations

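No further test was run in this part, and genes were grouped after their values were seen. Neuronal genes rose in several comparisons. The secretory granule gene CHGB rose after depletion of ZMYND8 (log2 2.88, adjusted p = 1.08e-04), ZNF655 (2.29, adjusted p = 3.47e-05) and ZNF608 (2.18, adjusted p = 2.72e-05), and with starvation of control (1.69, adjusted p = 3.65e-04) and HDGF-depleted cells (2.11, adjusted p = 0.00999). The last call was lost without HDGF library 3 or 4 or starved HDGF library 3. SYP rose in the same 3 depletions (0.91, 1.60 and 1.09), after INTS13 depletion (0.53) and with starvation of control (1.03), INTS13-depleted (0.64, lost without INTS13 library 3) and HDGF-depleted cells (0.84), and after ZEB1 depletion (0.31) in a call lost with the block (0.137) and without control 1b, control 2 or ZEB1 library 1. The list as a whole passed with an estimated correlation in the 3 depletions (adjusted p = 0.0475, 0.0177 and 0.021) but not with starvation of control cells (0.0687) or for ZNF655 against the controls labelled for ZMYND8 (0.291). It did not pass after INTS13 depletion, and the amounts of protein were not measured.

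SEC23A moved in more than 1 depletion. INTS13, HDGF and ZNF655 had controls in common, and so had the first-set depletions. In cells with glucose it fell after INTS13 (-1.52), TSPYL2 (-1.34) and ZNF655 depletion (-0.62) with each library left out in turn. Its falls after HDGF (-0.27) and ZEB1 depletion (-0.25) lost their calls, the former without either HDGF library, control 3b or control 4a, the latter with the block (0.138) and without control 1a, 1b or 2 or ZEB1 library 1. The ZNF655 call of SEC23A also passed against the controls labelled for ZMYND8 (adjusted p = 6.93e-06).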
